A study of Sphingomonas melonis TY with 9 samples.

How the data were processed

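RNA from Sphingomonas melonis TY was measured in 9 libraries, 3 for each of wild type (WT), an snc137 deletion with an empty vector (dsnc137) and the same deletion with a plasmid that overexpresses SNC137 (dsnc137_comp). Per the labels' protocols, RNA was depleted of rRNA and sequenced as 150 bp read pairs. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.3, counted per gene with HTSeq 0.6.1 and passed to DESeq, with no version given. The strand setting of the counting, the genome build and the step from counts to FPKM are not given in the sources used here. Genes that overlap, lie antisense to each other or are repeated are therefore uncertain in what follows.

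The deposited values are in FPKM, per the labels and as the authors processed them, for 4351 genes. In every library the value times gene length was a whole multiple of 1 step, within a tolerance of 0.001, for 100% of genes. Whole reads per gene could therefore be recovered, 2861521 to 3739251 per library, and were used for depth, detection and counting intervals. The FPKM were used as deposited for every fold change and test. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 4113 of 4351. This filter was chosen after the values were seen.

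Comparisons used 1 limma trend fit of all 9 libraries on log2(FPKM + 1), with Benjamini-Hochberg adjustment over all tested genes in each comparison and calls at an adjusted p below 0.05. A quasi-likelihood test of counts had been planned. It was replaced by limma because the unit was FPKM rather than counts, and neither edgeR nor DESeq2 was used for any value here. Fold changes are of FPKM + 1 on a log2 scale, and those given as "-fold" are ratios of mean FPKM. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

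There were 26 gene lists, made of words to be matched in gene symbols and products and written before the data were examined. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over lists with Benjamini-Hochberg, and with camera using an estimated correlation. Rotation tests (fry) were run beside them. Matching ignored case, so some lists took in unrelated products: phosphate uptake (49 genes) holds phosphorylases and siderophore receptors, and general stress (19 genes) holds hemN and hemF. With matching by case no list call changed.

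For a gene with 0 reads in a group, a bound ("at least N-fold lower") was set with 3 reads over the group. For 1 to 3 reads, the ratio is given with a 95% counting interval. These bounds and intervals cover counting error only. Adjacent genes called in the same direction were compared with 10000 permutations of gene order. Overlap between comparisons that share a group was set beside independence and beside 100 simulations without a true effect.

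Named genes were picked by rule: the 12 highest and 12 lowest called genes in each of the first 2 comparisons and 5 and 5 in the third (mean of at least 10 CPM, no overlap of replicates, rRNA and tRNA left out), up to 3 called members per direction of lists that passed or held at least 3 calls, members of the 3 longest runs, and ssrA with its neighbours. The same rule was then applied outside 2 segments that lost all reads. The segments, their use as a boundary and the singling out of ssrA were chosen after the values were seen. Replicate numbers come from the labels. The deviations of equally numbered libraries from their group means correlated at 0.11 to 0.40 for WT with dsnc137, over 0.1 in 3 of 3 pairs. This hints at pairing by number, though no label says why. It is not 1 to 1, as dsnc137 replicate 3 correlated more with WT replicate 2 (0.19) than with WT replicate 3 (0.11). There was no such hint for dsnc137 with dsnc137_comp (1 of 3 pairs, −0.20 to 0.18) or WT with dsnc137_comp (0 of 3, −0.19 to 0.05). The fit without the block, set before the values were seen, was kept.

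No library was left out of any group, and 104 genes with 0 reads in all libraries could not be tested.

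Alternatives were median-of-ratios scaling, library size only, no filter, a filter at 10 CPM, the replicate number as a block, only the 2 groups compared, a threshold on size, rRNA and tRNA left out, a pseudocount of 0.1 and each library left out in turn. Recovery was tested on simulated data: with changes added to part of 3886 genes, 94.0% of 67 genes at 2-fold and 49.3% of 67 at 1.5-fold were called between dsnc137 and WT, with 11 unchanged genes called. The simulation drew genes independently, with a common spread for all genes and no shift shared within a library. In the real data replicate 1 stood apart in each group, so these figures may be too favourable.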

Results

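Transcripts were measured in S. melonis TY with 3 libraries in each of 3 groups: WT, dsnc137 (deletion with empty vector) and dsnc137_comp (deletion with overexpression plasmid). All cells were grown in LB at 30 °C and collected at an OD600 of 0.6. Each library held 2861521 to 3739251 reads over genes, and 1 read in a 1-kb gene came to an FPKM of 0.270 to 0.338. Genes without reads numbered 154 to 187 per WT library, 365 to 375 in dsnc137 and 446 to 452 in dsnc137_comp. Replicate 1 stood apart from the other two in each group: the chi-square per degree of freedom between libraries was 18.5 and 20.7 for pairs with replicate 1 against 4.09 without it in WT, 12.7 and 15.2 against 5.41 in dsnc137, and 6.42 and 8.43 against 2.70 in dsnc137_comp. The labels do not say that the 3 replicates were separate cultures, so the p-values may only measure technical spread. Deletion and empty vector changed together between WT and dsnc137 and cannot be separated.

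The gene whose RNA followed the design was ssrA (BJP26_RS06610), annotated as transfer-messenger RNA, which frees stalled ribosomes and tags their unfinished proteins. Its FPKM was 4239 ± 589 in WT, 5.72 ± 2.55 in dsnc137 and 29276 ± 2619 in dsnc137_comp (SD, n = 3). This was 741-fold lower in dsnc137 (log2 fold change −9.35, SE 0.22, adjusted p = 1.95e-09) and 6.91-fold above WT in dsnc137_comp (adjusted p = 3.98e-06). Of 3533 genes with at least 100 reads in WT, 40 were below 1% of WT in dsnc137, 39 of them in 1 lost segment. Only ssrA was then above WT in dsnc137_comp. The annotation does not name SNC137, so the match of ssrA with it rests on this pattern alone.

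Of the genes beside ssrA, the pirin-family gene BJP26_RS06615, next downstream, changed most in dsnc137 and went from 172 ± 2.69 in WT to 1136 ± 169 in dsnc137 and 1046 ± 51.5 in dsnc137_comp (SD, n = 3). It was 6.61-fold higher (log2 2.71, SE 0.10, adjusted p = 1.72e-08) and stayed 6.09-fold above WT with the plasmid (adjusted p = 1.50e-08). Upstream, the Rrf2-family regulator BJP26_RS06605 was not called (0.05, adjusted p = 0.785). The channel gene mscL fell by 0.30 (adjusted p = 0.0199), but this call was lost without WT replicate 2 (0.0562) or dsnc137 replicate 2 (0.0765). Over all alternatives its adjusted p was 0.0163 to 0.129, the highest with library size as the only scaling. With the plasmid mscL rose by 0.31 (adjusted p = 0.0169; 0.0138 to 0.0888 over the alternatives), lost without dsnc137 replicate 2 (0.0713) and without dsnc137_comp replicates 1 (0.0596), 2 (0.0550) or 3 (0.0722). The tRNA-Phe gene BJP26_RS06620 was not called in dsnc137 (−0.33, adjusted p = 0.264) and fell by 0.89 with the plasmid (adjusted p = 0.0107; 4.85e-04 to 0.120 over the alternatives), and its log2 change against WT was −1.21 (adjusted p = 8.71e-04). Novel00118, on the opposite strand and overlapping ssrA, fell by 0.91 in dsnc137 (adjusted p = 0.00643) and rose by 3.54 with the plasmid (adjusted p = 3.00e-07). Reads of ssrA could enter that feature, as the strand setting is unknown.

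**Figure D1:**
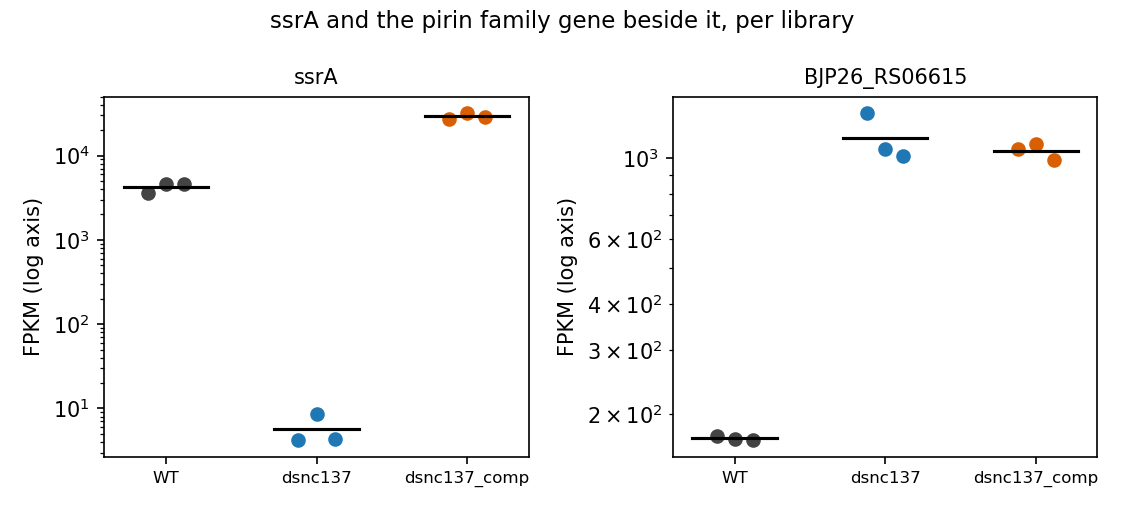
FPKM (log axis) of ssrA and of the downstream pirin-family gene BJP26_RS06615 in each library of WT, dsnc137 and dsnc137_comp; dots are libraries and black bars are means. ssrA was lost and then exceeded WT with the plasmid, while the pirin-family gene stayed high.

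A 200.8-kb segment that carries nicotine degradation genes lost its reads in both deletion groups. ndpC fell from an FPKM of 15.7 ± 1.69 in WT (SD, n = 3) to 0 in dsnc137 and in dsnc137_comp, at least 107.5-fold and 107.0-fold lower. ndpB was at least 56.4-fold lower and ndpD at least 17.4-fold lower in dsnc137. The segment's catalase BJP26_RS15265 (54.0 ± 10.9 in WT) was at least 394-fold lower, its formaldehyde dehydrogenase BJP26_RS15255 at least 378-fold, its ParA-family partition gene BJP26_RS19690 at least 293-fold and its siderophore receptor BJP26_RS15225 at least 172-fold. One gene, BJP26_RS15130, kept 1 read in dsnc137 and was 913.5-fold lower (counting interval 163.5 to 3.61e+04).

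The segment spans BJP26_RS14715 to BJP26_RS15735 and holds 222 genes. They shared 16045 reads in WT, 4 in dsnc137 and 2 in dsnc137_comp, or 1764 ± 43.3, 0.395 ± 0.342 and 0.180 ± 0.312 CPM (SD, n = 3). It holds 9 of the 13 genes of the nicotine degradation list, 14 mobile-element genes, 11 conjugation or type IV secretion genes, 4 toxin-antitoxin genes, 2 partition genes and the replication initiator BJP26_RS14750. All 149 tested genes in it were called lower in dsnc137 and in dsnc137_comp than in WT, and 0 differed between the deletion groups. As the segment was found by its few reads in each deletion group, these calls restate that choice and add no evidence of loss. The genes at the segment's edges have copies of equal length and product on both sides, a ParB-family gene (BJP26_RS14710 and BJP26_RS15760) and a metallopeptidase-domain gene (BJP26_RS14705 and BJP26_RS15755). These copies had 0 reads in all libraries, WT included, so the ends of the segment cannot be placed among them.

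A segment of 94.3 kb with polysaccharide genes lost its reads in dsnc137_comp alone. The tyrosine autokinase gene BJP26_RS13930 had an FPKM of 118 ± 7.34 in WT, 218 ± 36.7 in dsnc137 and 0 in dsnc137_comp (SD, n = 3), at least 1614-fold below dsnc137 and at least 873-fold below WT. The export gene BJP26_RS13935 was at least 477-fold below dsnc137 and the O-antigen ligase gene BJP26_RS13940 at least 318-fold. With 1 read left, asnB was 4112-fold below dsnc137 (counting interval 738 to 1.62e+05) and the UDP-ManNAc dehydrogenase gene BJP26_RS13950 was 4690-fold below (841 to 1.85e+05). In dsnc137 the same segment was above WT: BJP26_RS13960, a glycosyltransferase, rose by 1.13 (adjusted p = 5.32e-04), BJP26_RS13935 by 0.93 (adjusted p = 0.00196) and the relaxase gene BJP26_RS13875 by 1.23 (adjusted p = 8.97e-04).

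This segment runs from asnB to BJP26_RS13975 with 89 genes, 20 of them mobile-element genes, and holds the replication initiator BJP26_RS13635. Hypothetical protein genes of equal length lie on both sides of it too (BJP26_RS13565 and BJP26_RS13990, BJP26_RS13570 and BJP26_RS13995). Each had 0 or 1 read over all libraries. The segment had 28092 reads in WT, 51814 in dsnc137 and 10 in dsnc137_comp, or 3087 ± 49.9, 5126 ± 549 and 0.944 ± 0.833 CPM (SD, n = 3). Of its 76 tested genes, 40 were called higher in dsnc137 than in WT and 75 were called lower in dsnc137_comp than in dsnc137. The 75 restate how the segment was found, by few reads in dsnc137_comp. Both comparisons of dsnc137_comp therefore also carry the loss of this segment.

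**Figure D2:**
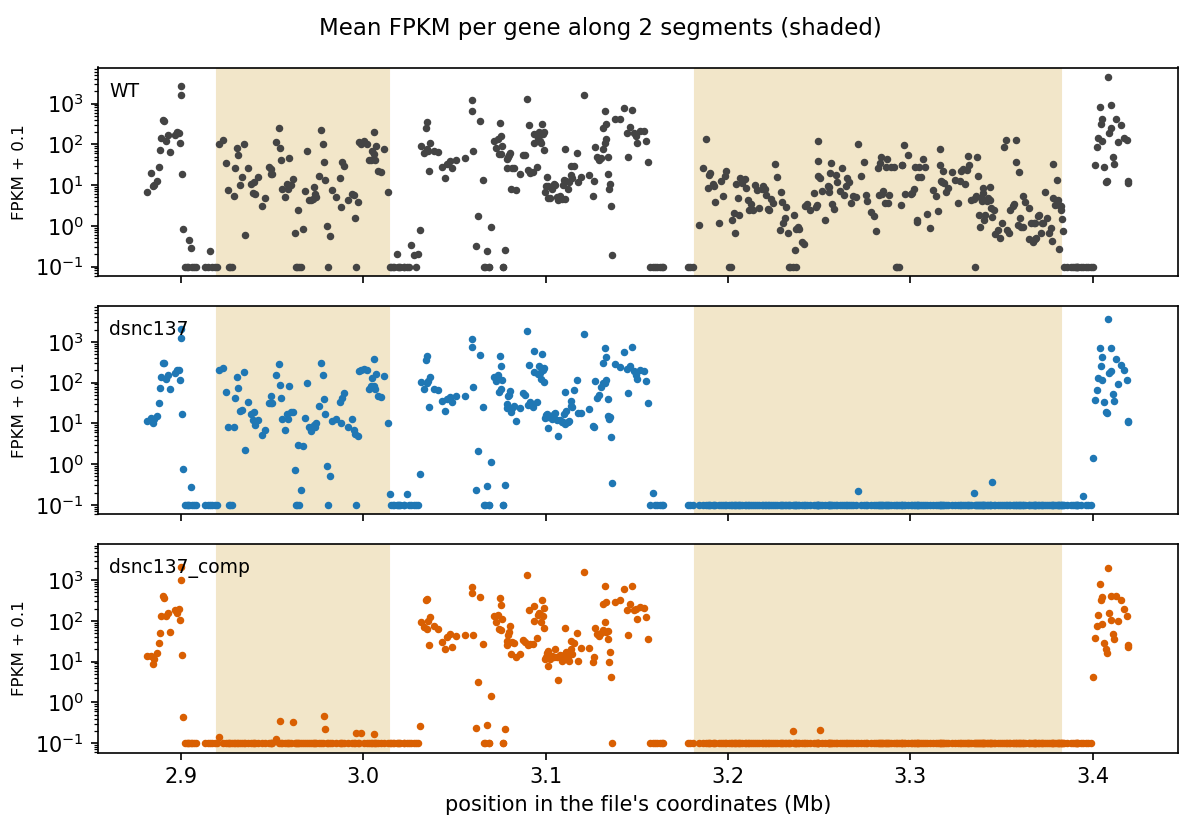
Mean FPKM + 0.1 (log axis) of each gene by position in the deposited coordinates in Mb, in 3 panels for WT, dsnc137 and dsnc137_comp, with the 2 segments shaded. The nicotine segment is empty in both deletion groups and the polysaccharide segment only in dsnc137_comp.

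Outside the 2 segments, an integrase locus and single genes of iron transport rose in dsnc137, although the iron uptake list had 9 of 38 genes lower there and 4 higher. The helix-turn-helix gene BJP26_RS04025 went from 157 ± 26.8 to 1420 ± 101 (SD, n = 3; 9.04-fold, log2 3.18, SE 0.16, adjusted p = 1.54e-07), and the integrase gene beside it, BJP26_RS04030, from 126 ± 0.619 to 499 ± 33.2 (3.95-fold, adjusted p = 9.71e-08). The adjoining tRNA-Leu BJP26_RS04035 rose by 0.84 (adjusted p = 0.00760). BJP26_RS14320, with a DUF736 domain, was 3.31-fold higher (adjusted p = 3.06e-07). An ABC transporter substrate-binding gene, BJP26_RS04960, rose by 1.05 (adjusted p = 2.35e-05) with its neighbour BJP26_RS04955, a TonB-dependent receptor (0.83, adjusted p = 6.44e-04). The siderophore receptor BJP26_RS10615 (0.93) and the ferrous iron transporter BJP26_RS02905 (0.75) also rose (adjusted p = 0.00231 and 0.00499).

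Single peroxide-detoxifying genes and a porin gene fell in dsnc137. Of the oxidative stress list, 8 of 23 genes outside the segments were called lower and 0 higher. The whole list did not pass camera with an estimated correlation (adjusted p = 0.287). The porin gene BJP26_RS10760 went from 317.5 ± 95.4 to 62.0 ± 6.21 (SD, n = 3; 5.12-fold lower, log2 −2.30, SE 0.19, adjusted p = 9.11e-06). The catalase/peroxidase BJP26_RS18015 was 3.11-fold lower (adjusted p = 1.68e-05) and ahpC, for alkyl hydroperoxide reductase, 2.51-fold lower (5162 ± 908 to 2058 ± 465, adjusted p = 7.53e-04). The glutathione-dependent formaldehyde dehydrogenase BJP26_RS08005 fell by 1.84 (adjusted p = 0.00142), the ferritin-like gene BJP26_RS02385 by 1.09 (adjusted p = 0.00331) and the xanthine dehydrogenase gene BJP26_RS12835 by 1.37 (adjusted p = 0.00202). Methionine synthases fell too, BJP26_RS13350 by 0.92 (1354 ± 192 to 716 ± 104, adjusted p = 8.97e-04) and metH by 0.90 (adjusted p = 0.00125).

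Ribosomal protein genes were higher in dsnc137 as a group, with 37 of 56 called higher and 0 lower (48 higher when adjusted over the list alone). rpsH rose 1.73-fold (1927 ± 215 to 3332 ± 453, SD, n = 3, adjusted p = 0.00200), rpsQ by 0.69 (adjusted p = 0.00218) and rpmC by 0.71 (adjusted p = 0.00220). Camera gave adjusted p = 1.59e-16, and alternatives ranged from 5.37e-21 to adjusted p = 0.564 with an estimated correlation. Flagellum and chemotaxis genes were also higher, 13 of 54 called higher and 0 lower (20 over the list alone): flgB rose by 0.85 (adjusted p = 0.00830), flgG by 0.51 (adjusted p = 0.00508) and flgF by 0.48 (adjusted p = 0.0101). Camera gave adjusted p = 8.04e-07 there, with alternatives from 7.92e-08 to adjusted p = 0.564 with an estimated correlation. With library size as the only scaling, the median of genes outside the segments moved to 0.104, and the medians of these lists went from 0.52 to 0.62 and from 0.32 to 0.42.

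Oxidative stress genes were lower, with 11 of 26 called lower and 0 higher (12 over the list alone; 8 of 23 outside the segments), at camera adjusted p = 7.50e-06 (alternatives from 3.38e-06 to adjusted p = 0.287 with an estimated correlation). Nicotine degradation had 9 of 12 lower (9 over the list alone), 8 of them in the lost segment, at adjusted p = 6.05e-07 (alternatives from 1.01e-08 to adjusted p = 0.145 with an estimated correlation). Mobile elements had 18 higher and 10 lower of 101 (19 and 10 over the list alone; 9 higher and 1 lower of 77 outside the segments), with a median of 0.25 but a mean of −0.04, and the fry direction was down. Their camera result, adjusted p = 0.0391 (alternatives from 0.00129 to 0.576 with an estimated correlation), was lost without WT replicate 1 (0.0878), dsnc137 replicate 2 (0.0821) or dsnc137 replicate 3 (0.113). Efflux had 3 higher and 3 lower of 42 (the same over the list alone) at adjusted p = 0.0452 (alternatives from 0.0140 to 0.287 with an estimated correlation). It was lost without WT replicates 1 (0.0590), 2 (0.0677) or 3 (0.0543) and without dsnc137 replicates 2 (0.0614) or 3 (0.113).

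Several lists held calls without passing as a list. Chaperones had 7 of 27 lower and 1 higher (12 and 1 over the list alone), among them dnaJ (−0.65, adjusted p = 0.00647), hslU (−0.69, adjusted p = 0.00859) and clpX (−0.45, adjusted p = 0.00829), at camera adjusted p = 0.171. With the replicate number as a block the chaperone list passed (0.0196), and over all alternatives its adjusted p was 0.00133 to 0.896. Fatty acid metabolism had 10 of 46 lower, such as the acyl-CoA dehydrogenase BJP26_RS01370 (−0.68, adjusted p = 2.97e-04), at 0.196. Iron uptake had 4 higher and 11 lower of 40 (7 and 11 over the list alone; 4 and 9 of 38 outside the segments) at 0.986, and TonB receptors 7 higher and 9 lower of 91 (7 and 3 of 83 outside the segments) at 0.344. The rRNA and tRNA list had 4 higher and 1 lower of 45 at 0.130. Pili (0.252), two-component systems (0.435), quorum sensing with cyclic di-GMP (0.462), translation factors (0.633), DNA repair (0.633), exopolysaccharide (0.684), TCA cycle (0.684), amino acid synthesis (0.686), respiration (0.689), general stress, nitrogen and sulfur, phosphate uptake, RNA decay and aromatic degradation (each 0.986) did not pass. Carotenoid synthesis had 3 genes, too few to test: crtY was not called (−0.03, adjusted p = 0.906), and the phytoene desaturase BJP26_RS05300 fell by 0.50 (adjusted p = 0.0131), and the phytoene/squalene synthase BJP26_RS05320 was not called (0.22, adjusted p = 0.224).

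In all, 834 of 4113 tested genes differed between dsnc137 and WT, 264 higher and 570 lower (1386 unadjusted). Of these, 225 changed at least 2-fold on the fitted scale, 27 higher and 198 lower. Only 67 of the 225 lay outside the 2 segments, 18 higher and 49 lower. Outside the segments 645 were called, 224 higher and 421 lower. Over all tested genes, the replicates of the groups did not overlap in 1397 (33.97%), where chance gives 10% for 3 against 3. This share includes the 149 tested genes of the nicotine segment, which was drawn by few reads in dsnc137. With library size as the only scaling the calls split 452 higher and 427 lower, so the excess of lower genes depends on the scaling.

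**Figure D3:**
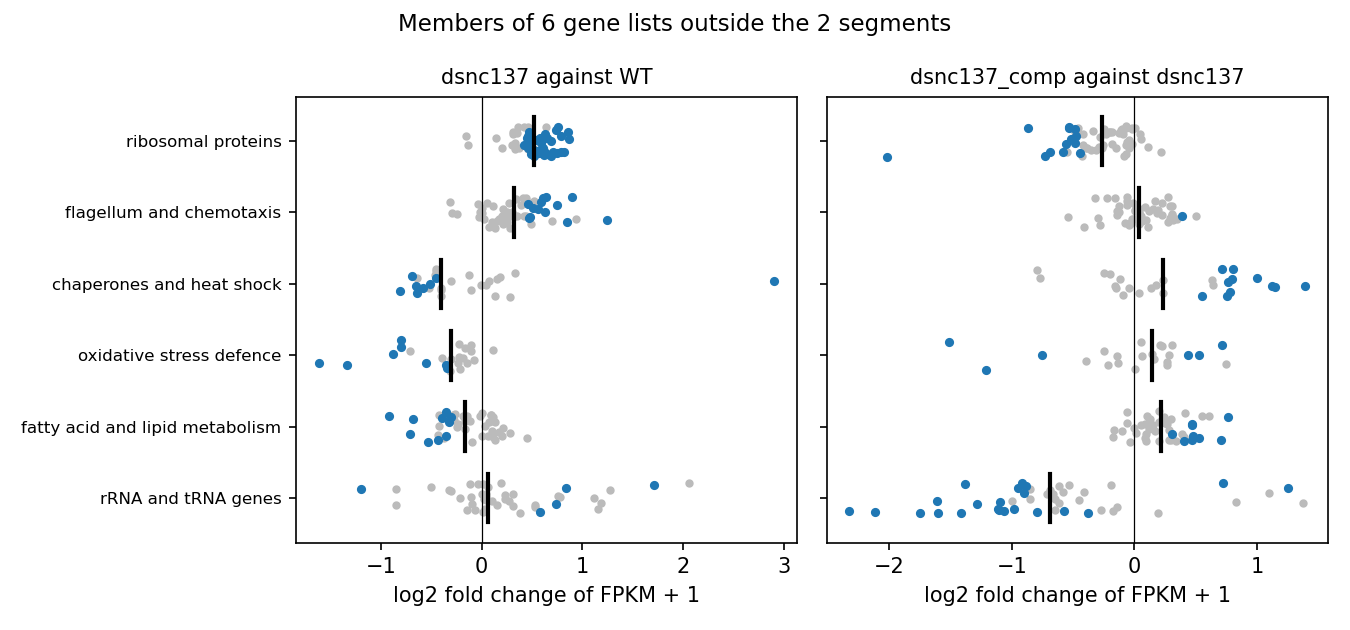
Log2 fold change (FPKM + 1) of the members of 6 gene lists outside the 2 segments, for dsnc137 against WT and dsnc137_comp against dsnc137; blue dots have adjusted p below 0.05, grey dots do not, and black bars are medians. In dsnc137, 37 of 56 ribosomal and 13 of 54 flagellar genes were called higher; with the plasmid, 11 of 27 chaperone genes were called higher and 20 of 45 rRNA and tRNA genes lower. With an estimated correlation none of these lists passed (0.564, 0.564, 0.545 and 0.123).

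With the plasmid, 11 of 27 chaperone genes rose above dsnc137 and 16 were not called; the list did not pass with an estimated correlation (0.545). dnaJ went from 474.5 ± 55.5 to 1245 ± 167 (SD, n = 3; 2.62-fold, log2 1.39, SE 0.13, adjusted p = 4.43e-05), dnaK was 2.18-fold higher (3176 ± 525 to 6920 ± 1103, adjusted p = 0.00160), hslU rose by 1.14 (adjusted p = 4.77e-04) and clpX by 0.76 (adjusted p = 3.96e-04). The metallo-beta-lactamase gene bla rose 3.19-fold (55.8 ± 4.13 to 178 ± 11.8, adjusted p = 9.47e-06). The TonB-dependent receptor BJP26_RS13245 rose 3.58-fold (149 ± 29.5 to 533 ± 64.1, adjusted p = 1.13e-05) and the helix-turn-helix gene BJP26_RS00450 by 2.58 (adjusted p = 7.70e-04). Acyl-CoA dehydrogenase BJP26_RS01370 rose by 0.70 (adjusted p = 2.97e-04), and argF by 0.58 (adjusted p = 0.00373).

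Other genes fell with the plasmid. BJP26_RS07300, a hypothetical protein gene, went from 602 ± 135 to 73.5 ± 38.0 (SD, n = 3; log2 −3.15, SE 0.36, adjusted p = 2.01e-04) and was 20.8-fold below WT. The response regulator BJP26_RS09165 fell from 519 ± 22.1 to 115 ± 7.52 (−2.16, adjusted p = 6.35e-08) and rimO, which methylthiolates ribosomal protein S12, from 148 ± 18.0 to 35.6 ± 2.55 (−2.02, adjusted p = 8.83e-07). The catalase genes BJP26_RS19040 (−1.51, adjusted p = 0.00246) and BJP26_RS16910 (−1.21, adjusted p = 0.00260) and aspS, for aspartyl-tRNA ligase (−0.92, adjusted p = 1.27e-04), were also lower. The helix-turn-helix gene BJP26_RS04025 and the integrase gene BJP26_RS04030 fell by 2.42 and 1.26 (adjusted p = 2.38e-06 and 6.05e-06) but were still above WT, by 0.75 (adjusted p = 0.00570) and 0.71 (adjusted p = 2.14e-04).

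Transfer RNAs were lower with the plasmid, 20 of 45 in the rRNA and tRNA list called lower and 2 higher (21 and 2 over the list alone), with a median of −0.69. Other genes of at most 150 bp outside the segments were also lower in part, 63 of 86 with a negative change and a median of −0.27. tRNA-Ala BJP26_RS00405 went from 714 ± 38.6 to 239 ± 50.4 (SD, n = 3; 2.99-fold lower, adjusted p = 2.65e-05), tRNA-Leu BJP26_RS02980 fell by 1.09 (adjusted p = 1.08e-05) and tRNA-Gly BJP26_RS16855 by 0.98 (adjusted p = 3.25e-05), while tRNA-Leu BJP26_RS17960 rose by 0.72 (adjusted p = 0.00509; 0.00198 to 0.0562 over the alternatives, the highest with voom). tRNAs were 0.0768% of reads in WT, 0.0948% in dsnc137 and 0.0516% in dsnc137_comp. Camera gave adjusted p = 3.59e-06, and alternatives ranged from 9.55e-10 to adjusted p = 0.123 with an estimated correlation.

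Chaperones had 11 of 27 higher and 0 lower (12 over the list alone) at camera adjusted p = 2.18e-04 (alternatives from 5.86e-06 to adjusted p = 0.545 with an estimated correlation). Fatty acid metabolism had 9 of 46 higher and 0 lower (11 over the list alone), at adjusted p = 7.06e-05 (alternatives from 1.60e-05 to adjusted p = 0.123 with an estimated correlation). Ribosomal protein genes, higher in dsnc137, had 13 of 56 lower (19 over the list alone), among them ykgO (−0.87, adjusted p = 6.14e-04) and rpmH (−0.56, adjusted p = 0.00356), at adjusted p = 9.11e-05 (alternatives from 1.32e-07 to adjusted p = 0.679 with an estimated correlation). rimO sits in that list but modifies a ribosomal protein.

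Exopolysaccharide had 8 lower and 1 higher of 42 at adjusted p = 0.0213 (0.123 with an estimated correlation, and 2.14e-04 to 0.290 over the alternatives), 4 of the 8 outside the segments, and this was lost without dsnc137 replicate 3 (0.0604). Mobile elements had 21 lower and 7 higher at adjusted p = 0.0213 (0.545 with an estimated correlation, and 5.40e-04 to 0.952 over the alternatives), with 6 lower and 7 higher outside the segments, and this was lost without dsnc137 replicate 3 (0.0730). The TCA cycle list passed at adjusted p = 0.0225 (alternatives from 7.41e-04 to 0.640 with an estimated correlation) with 1 gene called, leuA, which makes leucine rather than a TCA intermediate; it was lost without dsnc137 replicates 2 (0.0741) or 3 (0.108). Amino acid synthesis had 6 of 59 higher at adjusted p = 0.0372 (alternatives from 0.00199 to 0.679 with an estimated correlation), but its median of 0.06 turned to −0.02 with library size as the only scaling. It was lost without dsnc137 replicates 2 (0.155) or 3 (0.114) and without dsnc137_comp replicates 1 (0.0830) or 2 (0.0668). The other 17 lists did not pass, with adjusted p = 0.0726 for two-component systems to 0.743 for TonB receptors. In all, 714 genes differed between dsnc137_comp and dsnc137, 230 higher and 484 lower (1208 unadjusted), 639 of them outside the segments. At least 2-fold on the fitted scale were 235, of which 160 lay outside the segments. The count of 714 was 440 without dsnc137_comp replicate 2 and 473 without dsnc137_comp replicate 3. The split was 155 higher and 625 lower with library size as the only scaling. Over all tested genes the replicates did not overlap in 1385 (33.7%, against 10% by chance). Counted in this share are the 76 tested genes of the polysaccharide segment, which was drawn by few reads in dsnc137_comp.

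Against WT, genes of several groups changed in dsnc137 were also called in dsnc137_comp. Flagellum and chemotaxis genes had 17 of 54 higher and 0 lower (21 over the list alone), with the hook gene BJP26_RS04650 up 0.76 (475 ± 33.98 to 806 ± 56.7, SD, n = 3, adjusted p = 8.38e-04) and flgG up 0.82 (adjusted p = 1.14e-04). The porin gene BJP26_RS10760 was 9.01-fold lower (adjusted p = 4.89e-07), ahpC 4.30-fold lower (adjusted p = 1.22e-05) and BJP26_RS08005 lower by 3.70 (adjusted p = 3.42e-06). Ribosomal protein genes had 21 of 56 higher and 3 lower (25 and 3 over the list alone), with rpsQ up 0.67 (adjusted p = 0.00139). Their median was 0.29, against 0.52 in dsnc137, and 13 were lower and 0 higher in dsnc137_comp than in dsnc137 (camera adjusted p = 9.11e-05; 0.679 with an estimated correlation). Other changes against WT were not called in dsnc137: rpmG was lower by 0.82 (adjusted p = 0.00218; −0.13, adjusted p = 0.575 in dsnc137) and the cold-shock gene BJP26_RS11280 by 0.77 (adjusted p = 4.48e-04; −0.26, adjusted p = 0.132 in dsnc137).

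Camera adjusted p was 1.94e-07 for flagellum and chemotaxis (alternatives from 3.70e-08 to 0.518 with an estimated correlation), 6.19e-05 for ribosomal proteins (5.90e-08 to 0.632) and 1.54e-04 for nicotine degradation (1.19e-05 to 0.422; 8 of 12 lower, all 8 in the nicotine segment and 0 of the 4 outside). Weaker results were oxidative stress (adjusted p = 0.0308, 10 lower and 1 higher of 26, or 7 and 1 of 23 outside the segments), amino acid synthesis (0.0309, 5 higher and 0 lower), rRNA and tRNA (0.0309, 19 lower and 1 higher), pili (0.0339, 6 higher and 4 lower of 41, or 6 and 1 of 38 outside the segments) and chaperones (0.0339, 6 higher and 1 lower). With an estimated correlation these 5 had adjusted p of 0.519, 0.632, 0.506, 0.506 and 0.632, and their lowest over the alternatives were 0.00110, 0.00675, 2.58e-05, 0.00324 and 0.00235. Oxidative stress was lost without dsnc137_comp replicate 1 (0.0529). Amino acid synthesis was lost without WT replicate 2 (0.0692) or dsnc137_comp replicate 2 (0.0524), and rRNA and tRNA without either (0.0692 and 0.0524) or WT replicate 1 (0.0653). Pili was lost without WT replicates 1 (0.0653) or 3 (0.0565) or dsnc137_comp replicate 1 (0.0651), and chaperones without WT replicate 1 (0.106) or dsnc137_comp replicates 2 (0.0889) or 3 (0.0944). The other 17 lists did not pass; the lowest was translation factors (0.0554), which passed without WT replicate 1 (0.00821), dsnc137 replicate 1 (0.0432) or dsnc137_comp replicate 3 (0.0308), and the TCA cycle passed without WT replicate 1 (0.0423). In all, 1023 genes differed, 241 higher and 782 lower (1469 unadjusted), 800 of them outside the segments. At least 2-fold were 487, of which 264 lay outside the segments. Over all tested genes the replicates did not overlap in 1753 (42.6%, against 10% by chance). Counted in this share are the 149 and 76 tested genes of the 2 segments, which were drawn by few reads in dsnc137_comp.

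Many genes lowered in dsnc137 rose with the plasmid. Outside the segments, 114 genes fell and then rose, among them dnaJ, hslU, clpX, argF, BJP26_RS01370 and BJP26_RS13350 (+0.72, adjusted p = 0.00433), where independence gave 24.9. Another 52 rose and then fell, such as BJP26_RS04025, BJP26_RS04030 and BJP26_RS14320 (−1.39, adjusted p = 3.17e-06), where independence gave 23.6. A further 84 fell both times, such as BJP26_RS08005 and BJP26_RS12835 (−1.01, adjusted p = 0.0117), against 44.3, and 0 rose both times, against 13.3. Simulations without a true effect gave 0 such genes. They gave every group the same mean for each gene, so almost no gene could be called. This 0 was fixed by their setting and does not bound the overlap that shared libraries make among changed genes. Part of the excess in these counts may come from the shared dsnc137 libraries. Fold changes correlated at −0.25 against −0.50 in the simulations, with a covariance of −0.0536 against −0.0208 (difference −0.0328). Over all genes the opposite overlap was 206, but 340 with the replicate number as a block, 126 with only the 2 groups compared, 108 without dsnc137 replicate 2, 116 without dsnc137_comp replicate 2 and 120 without dsnc137_comp replicate 3. The same-direction overlap of 84 was 44 without dsnc137 replicate 3, 48 without dsnc137 replicate 2 and 54 without dsnc137_comp replicate 1 or 2.

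Of the 645 genes called in dsnc137 outside the segments, 307 (47.6%) were still called in the same direction in dsnc137_comp against WT, such as BJP26_RS06615, BJP26_RS10760 and rpsQ. Another 15 were called in the opposite direction, dnaJ among them (0.74, adjusted p = 0.00178), and 323 were not called, such as argF (0.07, adjusted p = 0.685). Both comparisons used the same WT libraries, and part of the overlap may come from them. Independence gave 74.4 genes in the same direction and 58.3 in the opposite one. Simulations without a true effect gave 0 of either, again fixed by their setting. Fold changes outside the segments correlated at 0.56 against 0.50 in the simulations, with a covariance of 0.140 against 0.0206 (difference 0.119). In the direction of the change in dsnc137, the median log2 change of the 645 genes was 0.58 in dsnc137 and 0.36 in dsnc137_comp. Genes chosen by their change in dsnc137 shrink in part by that choice alone. A gene called in 1 comparison and not in another is not thereby shown to differ between them.

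Changed genes lay side by side. In dsnc137 against WT outside the segments, 19 genes in a row from rpmD to rplC rose (median 0.62). A run of 8 features around the xanthine dehydrogenase BJP26_RS12835, some of them without a locus tag, fell (median −1.08). Adjacent pairs called in the same direction numbered 207, 182 and 295 outside the segments in the 3 comparisons, against permutation means of 58.3, 56.5 and 95.1. All permutation p were 1e-04, the smallest they can give. Over all genes the pairs were 381, 255 and 515, and the count of 255 became 153 without dsnc137_comp replicate 2 and 162 without dsnc137_comp replicate 3. Pairs and runs count features without a locus tag, which were 324 of the 4113 tested and 68, 83 and 107 of the calls in the 3 comparisons. As the strand setting is unknown, such features may share reads with their neighbours, which could raise these counts.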

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

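Of the alternatives below, voom on the recovered reads, leaving out the 2 segments, features without a locus tag or the 3 libraries numbered 1, the replicate block with only the 2 groups compared, and matching lists by case were chosen after seeing the data. Counts of called genes stayed within 1.5 times of the reported ones under median-of-ratios scaling (832, 708 and 1020), library size only (879, 780 and 1038), no filter (871, 698 and 1054), 10 CPM (725, 721 and 861), a pseudocount of 0.1 (823, 703 and 1015), voom (892, 746 and 1063) and without the libraries numbered 1 (830, 799 and 939; 7 lists gained and 2 lost). Of 385 calls of the 266 genes under the naming rule, 0 reversed in 23 settings, but many were lost: 24 to 75 with 1 library left out (75 without dsnc137_comp replicate 2, 61 without dsnc137 replicate 2), 47 without the libraries numbered 1, 45 with only the 2 groups compared, 42 when these were also blocked, 20 without the segments, 19 with library size only, 4 with the block and 193 at an absolute log2 change of 1. The other 7 settings lost 0 to 6 each. That 0 reversed says little, as few settings could change a sign. Filters, blocks, fits of 2 groups and the size threshold leave the fold changes as they were. Leaving out 1 library cannot reverse a gene whose replicates do not overlap between groups. This held for 820 of 834, 714 of 714 and 1020 of 1023 called genes in the 3 comparisons.

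With 1 library left out, calls ranged over 585–780, 440–795 and 806–1120 in the 3 comparisons, the opposite overlap over 108–237, the same-direction overlap over 44–73, genes still called against WT over 48.3–62.1% (54.7% with all libraries, segments included), adjacent pairs over 276–357, 153–299 and 409–549, and lists past the threshold over 4–6, 4–11 and 5–9. For dsnc137_comp against dsnc137, 4 lists passed without dsnc137 replicate 3, and for dsnc137_comp against WT 5 passed without dsnc137_comp replicate 2, rather than 8 each.

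Requiring an absolute log2 change of at least 1, which keeps fewer genes by construction, left 225, 235 and 487 calls, overlaps of 16 (opposite) and 14 (same), 84.0% still called against WT (segments included) and 164, 117 and 307 adjacent pairs. Outside the segments these were 67, 160 and 264 calls and 12, 44 and 87 adjacent pairs. With replicate number as a block, calls were 1058, 931 and 1195 and the opposite overlap 340; with only the 2 groups compared it was 126, and blocked as well 191 with 1079, 519 and 1042 calls; the cause was not tested. Of 9 libraries, 6 correlated best with their own number, a hint from the data rather than the design. The hint of pairing held for WT with dsnc137 only, where blocking raised the calls without moving them over 1.5 times. There, chaperones passed camera with the block (0.0196), BJP26_RS11870 lost its call (0.0560), and no other camera list or call under the naming rule changed.

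Without the 2 segments, which removes their genes by construction, adjacent pairs were 192 (dsnc137 against WT) and 268 (dsnc137_comp against WT), and 5 lists passed for dsnc137_comp against dsnc137 rather than 8. Mobile elements then turned upward in dsnc137_comp against dsnc137 (0.952) and against WT (0.00870). With an estimated correlation 0 lists passed camera in each comparison. Fry with the replicate block passed 14 lists for dsnc137 against WT, 9 for dsnc137_comp against dsnc137 and 13 for dsnc137_comp against WT. Against camera it reversed two-component systems (0.0284) and mobile elements (0.0291) in dsnc137 against WT, and phosphate uptake (0.00500) and DNA repair (0.00135) in dsnc137_comp against WT. Fry without the block also gave these lists as down (adjusted p = 0.00131, 0.0194, 0.001485 and 3.455e-04, in that order). The block is therefore not what turned them, and why fry and camera differ was not tested. Without features lacking a locus tag 5 lists passed for dsnc137_comp against WT, for a cause not tested.

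Not run were the DESeq2 test, TMM scaling and a surrogate variable, all planned for counts rather than FPKM.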

Other observations

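Except for the loss of short RNA and the splits of the libraries, the tests in this part were chosen after the result was seen, as were the genes named in its first 2 paragraphs, apart from the pili, diguanylate cyclase, HdeA and efflux genes. raiA, which encodes a factor that binds idle ribosomes, fell from an FPKM of 3571 ± 177 in WT to 1559 ± 117 in dsnc137 and rose to 2579 ± 307 in dsnc137_comp (SD, n = 3; −1.20, adjusted p = 2.59e-05, then 0.72, adjusted p = 0.00148). The SulP-family anion transporter gene BJP26_RS04820 rose from 258 ± 26.8 to 449 ± 50.9 in dsnc137 (0.79, adjusted p = 5.47e-04), and the divalent metal transporter gene BJP26_RS18980 fell from 378 ± 11.6 to 165.5 ± 12.6 (−1.19, adjusted p = 2.67e-06). Genes of the tmRNA and small RNA machinery were not called between dsnc137 and WT: smpB (−0.12, adjusted p = 0.747), hfq (0.08, adjusted p = 0.688) and rnpB (−0.06, adjusted p = 0.863). The signal recognition particle RNA ffs was lower in dsnc137_comp than in dsnc137 (−0.91, adjusted p = 3.36e-04).

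Against WT, dsnc137_comp had lower RNA of a run from treZ to BJP26_RS12960, with malQ and an alpha-amylase among its 6 genes (median −1.24), and of 7 genes from BJP26_RS19010 to the catalase BJP26_RS19040 (median −1.11). The glycoside hydrolase BJP26_RS13240, beside the receptor BJP26_RS13245, rose by 1.17 over dsnc137 (adjusted p = 4.26e-04). The pilus assembly genes BJP26_RS01055 (CpaD family, 0.77, adjusted p = 0.00291) and BJP26_RS01050 (0.61, adjusted p = 0.00954) were above WT, as was the efflux gene BJP26_RS10910 (1.07, adjusted p = 0.00175). The diguanylate cyclase BJP26_RS02215 (−0.99, adjusted p = 0.00325) and the HdeA-family chaperone BJP26_RS05980 (−1.06, adjusted p = 0.00886) were below it.

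The nicotine segment had 4 reads left in dsnc137. These are 0.0225% of the WT reads scaled by the FPKM denominators, or 0.0241% when scaled by total reads. The segment was drawn from genes with at most 3 dsnc137 reads each, so these shares were low by construction and decide nothing. Lower depth is argued against by the group totals, 9396012 reads over genes in dsnc137 and 9070230 in WT. A general loss of weak genes is argued against too, since 0% of 922 genes outside with as few WT reads were at 0 in dsnc137. Absence of the DNA segment and transcriptional silencing with the DNA kept cannot be told apart, because RNA alone was measured. That 98.1% of its genes with at least 10 WT reads (156 of 159) were at 0 restates how the segment was drawn, by few reads, and supports neither. Under either, loss of this RNA may be part of any difference between dsnc137 and WT.

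The polysaccharide segment was higher in dsnc137 than in WT, with a median log2 change of 0.72 over 76 genes. The median of genes outside the segments was 0.00358. The FPKM denominators were 0.948 to 1.13 times the read totals, so the scaling itself may set this median near 0. With library size as the only scaling it was 0.104, below the segment's 0.72 in the reported fit. This argues against scaling of the libraries as the whole cause. A change confined to the outer genes of the segment is argued against by a median of 0.60 over the 58 genes between them, beside 0.84 over the 18 outer genes. The outer genes were those before BJP26_RS13595 or after BJP26_RS19635, limits set by hand. No operon was mapped, so regulation of polysaccharide operons as such was not tested. More copies of the whole segment may contribute, but no value here decides. That 98.7% of its tested genes (75 of 76) had a positive change, 40 of them called, restates the pattern and does not measure copies. DNA was not measured, so more copies stay a hypothesis.

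Lower tRNA in dsnc137_comp was not due to a few abundant tRNA genes, since 86.7% of the tested ones (39 of 45) had a negative change against dsnc137. Of the 45, 20 were called lower and 2 higher. Loss of short RNA in library preparation may contribute: the 86 other genes of at most 150 bp had a median of −0.27, with a negative change in 63. This median lay between the values set beforehand for and against such a loss, so it cannot be told apart. An effect of the overexpressed transfer-messenger RNA on tRNA may contribute too, but 0 groups had ssrA above its WT level and kept the polysaccharide segment.

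For each comparison, 1 of the 10 splits of its 6 libraries, the real one, gave as many genes: 834 with 1 as the highest other, 714 with 1, and 1023 with 0. With 10 splits a share under 0.05 cannot be reached.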
